A study of Mus musculus with 30 samples.

How the data were processed

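The samples are pieces of subcutaneous MC38 tumours grown in female C57BL/6 mice. MC38 is a mouse colon carcinoma line. Tumours came from wild-type cells (WT) or from cells carrying loss-of-function mutations in B2m (B2mKO) or Jak1 (Jak1KO). Mice received 100 µg of an antibody against the checkpoint receptor PD-1 (aPD1) or of an IgG1 control on days 7, 10 and 13 after inoculation, and tumours were taken on day 14. RNA was extracted from about 50 mg of tissue, per the labels' protocols, and libraries were made with a TruSeq RNA kit and sequenced as paired ends. There are 30 libraries in 6 groups of 5. The labels do not state that each library came from a different mouse, so p-values measure the spread between these samples.

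The deposited values are raw gene counts for 55471 Ensembl genes. They were made by the authors with featureCounts 2.0.0 on the Ensembl GRCm38 release 99 annotation, without strand and without reads that map to several places, per the file headers. FastQC 0.11.2, STAR 2.5.2a, Cufflinks 2.2.1, edgeR 3.24.3 and the mm10 build are named in the submitters' processing notes, with no parameters. The 30 per-sample tables held the same counts as the table of the whole series. For 1 library (WT aPD1 replicate 2) the header names an alignment file with another name than the sample's own, and its counts were used as deposited. Because the kit and the counting ignore strand, reads from overlapping genes on opposite strands could not be separated. Genes with near-identical copies (the granzyme cluster, Ifit3 and Ifit3b, the H2-Q genes, Tgtp1 and Tgtp2, the Gbp genes) lose reads that fit several copies, so their values are uncertain.

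Total counts per library were between 17629795 and 25944701. Every one of the 60 pairs of replicates differed by more than sampling noise (chi-square per degree of freedom 6.5 to 205.8 over genes with at least 10 counts), so no library was counted as a repeat of another. Gene symbols came from a reference table matched on the Ensembl identifier; 55144 identifiers had a symbol, and the other 327 held 0.047% of counts. Coordinates are those in the files (GRCm38).

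Everything else was computed here in R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0. Groups were taken from the labels. Genes were kept by edgeR's filterByExpr by group (minimum count 10, minimum total 15), which left 15505. Libraries were scaled by TMM (factors 0.939 to 1.043). All 30 libraries entered 1 quasi-likelihood fit with 6 group means, and each comparison was tested with edgeR's quasi-likelihood F-test and Benjamini-Hochberg adjustment over all genes tested. The threshold was an adjusted p under 0.05. Standard errors (SE) are the absolute log2 fold change divided by the square root of F. Levels are given in edgeR's CPM, a gene's counts relative to the library's scaled total. On simulated counts with known changes, the same steps recovered 50.7%, 67.2% and 97% of genes changed 1.5, 2 and 4 times in the comparison of aPD1 with IgG1 in WT tumours (15328 genes), 49.3%, 67.2% and 92.4% in the comparison of B2mKO with WT tumours under IgG1 (15321 genes), and 19.4%, 53.7% and 81.8% in the test of whether the aPD1 effect differed between B2mKO and WT tumours (15315 genes). In the same order, 11 of 171, 13 of 167 and 6 of 122 calls were false. The simulated genes varied independently and no simulated library stood apart, unlike the real data.

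Gene lists (44 lists, 750 genes) for proteases, their inhibitors, immune pathways and the cell types of a tumour were fixed before the data were examined. Of these, 42 were tested; mammary epithelium and skin and hair keratinocytes were not, with 3 and 4 expressed genes, under the minimum of 5. Of the list genes, 2 were matched through a synonym and 3 had no match. Lists were tested with limma's camera on log2 CPM (prior count 2) with a preset inter-gene correlation of 0.01, adjusted over the lists. With an estimated correlation, camera kept 1 list call over all comparisons (TGF-beta target genes, B2mKO against Jak1KO tumours under aPD1). The fry rotation test and, chosen after seeing the data, an exact two-sided permutation of list means (5 against 5 libraries) are given for comparison. A list's members are counted past the threshold over all genes and adjusted over the list alone. The lists of proteases together hold 139 expressed genes.

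The rule for named genes was also fixed beforehand. It takes B2m and Jak1 in each comparison; up to 6 genes with the largest rise and 6 with the largest fall among those past the threshold, with at least 5 CPM in the higher group and all 5 libraries on the same side of the other group's median; up to 4 members with the smallest p per reported list and up to 10 over the protease lists; and, for differences between effects, the 6 genes with the smallest adjusted p. Predicted genes were skipped, and a few of the genes that the rule takes are not reported. For genes with at most 3 counts in a whole group, the ratio of CPM with a 95% exact counting interval is given in place of the fitted value, and with no counts a bound from 3 counts over the group. These intervals and bounds cover counting error only. B2m and Jak1 were also tested by exact two-sided permutation of 5 against 5 libraries, for which the smallest possible p is 0.00794.

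The alternatives planned beforehand were DESeq2 size factors, library totals alone, 2 other filters on low counts, edgeR's older quasi-likelihood test, DESeq2's Wald test, limma voom, a fit of only the groups compared, stricter thresholds, the provider's library number as a covariate, the replicate number as a block, and leaving out each replicate. Those chosen after seeing the data were leaving out WT IgG1 replicate 3 and B2mKO aPD1 replicate 2 together, removing a trend with transcript length, and the permutation of list means.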

Results

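RNA was sequenced in 30 libraries from MC38 tumours that differed in genotype and in antibody treatment. WT, B2mKO and Jak1KO tumours were each sampled with aPD1 and with IgG1, with 5 libraries per group, so n = 5 per group in every comparison. B2m encodes the invariant light chain of MHC class I, and Jak1 encodes a kinase that transmits interferon signals. Loss of either is a known route to resistance to checkpoint blockade. The series is titled for protease dysregulation in response and resistance, so protease genes are followed through each comparison. Total counts per library were 17833233 to 23938816 in the WT IgG1 group and 17983200 to 25658875 in the WT aPD1 group. They were 18599575 to 25944701 for B2mKO IgG1 and 18881630 to 23161312 for B2mKO aPD1, and 17629795 to 23482943 for Jak1KO IgG1 and 19987329 to 23090261 for Jak1KO aPD1. Changes are log2 fold changes ± SE from edgeR's quasi-likelihood test with Benjamini-Hochberg adjusted p.

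The targeted genes were low in the tumours labelled as their knockouts. B2m (ENSMUSG00000060802, chromosome 2, 122147686 to 122153083, GRCm38) was at 3090 ± 911 CPM (SD, n = 5) in WT tumours with IgG1 and at 617 ± 112 CPM in B2mKO tumours, a change of -2.32 ± 0.19 (edgeR adjusted p = 9.04e-10). With aPD1 the levels were 4570 ± 728 and 749 ± 160 CPM (-2.61 ± 0.20, edgeR adjusted p = 1.14e-10). Jak1 (ENSMUSG00000028530, chromosome 4, 101152367 to 101265282) was at 232 ± 28.7 CPM in WT and 71.5 ± 4.98 CPM in Jak1KO tumours with IgG1 (-1.70 ± 0.10, edgeR adjusted p = 1.78e-12), and at 239 ± 6.09 and 72.4 ± 6.99 CPM with aPD1 (-1.72 ± 0.10, edgeR adjusted p = 1.65e-12). Each of these 4 differences reached the smallest exact permutation p, 0.00794 (0.0159 after adjustment over the permutation tests of both genes). The remaining level was 20.0% and 16.4% of WT for B2m and 30.8% and 30.3% for Jak1. The tumours also hold host cells that carry both genes. B2m, which interferon induces, was also lower in Jak1KO than in WT tumours, at 1200 ± 92.9 CPM with IgG1 (-1.36 ± 0.19, edgeR adjusted p = 5.92e-06) and 1250 ± 309 CPM with aPD1 (-1.87 ± 0.19, edgeR adjusted p = 2.84e-08). Jak1 was higher in B2mKO than in WT tumours with IgG1 (303 ± 19.1 CPM; 0.38 ± 0.10, edgeR adjusted p = 0.00696), and with aPD1 the difference did not pass (278 ± 45.6 against 239 ± 6.09 CPM; 0.22 ± 0.10, edgeR adjusted p = 0.125).

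**Figure D1:**
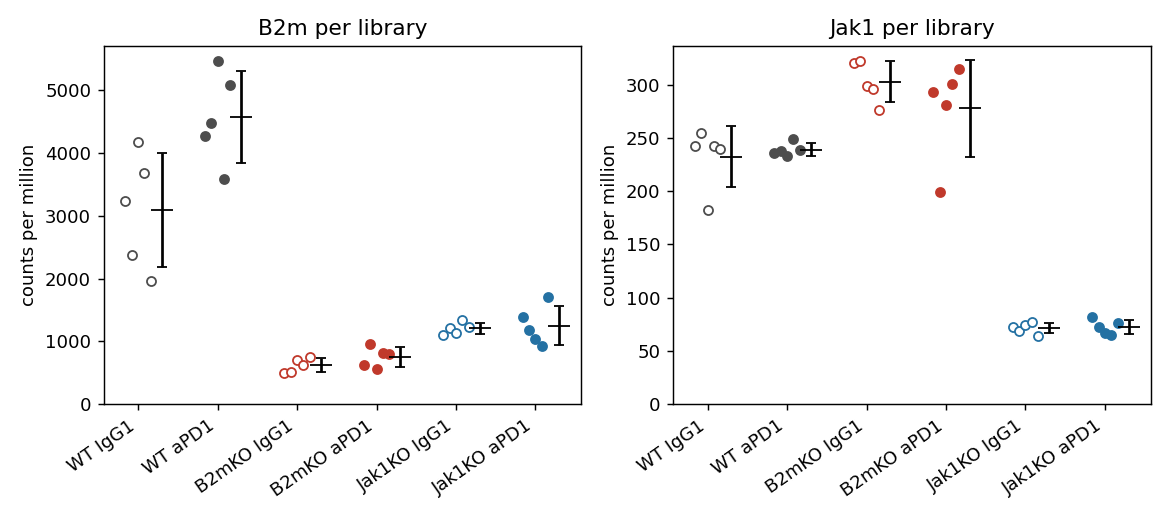
B2m (left) and Jak1 (right) in CPM for each of the 30 libraries; open circles are IgG1, filled circles aPD1, and the line and bars beside each group its mean ± SD (n = 5). B2m lay between 501 and 963 in the 10 B2mKO libraries, and Jak1 between 64.4 and 81.9 in the 10 Jak1KO libraries, below every library of the WT groups.

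**Figure D2:**
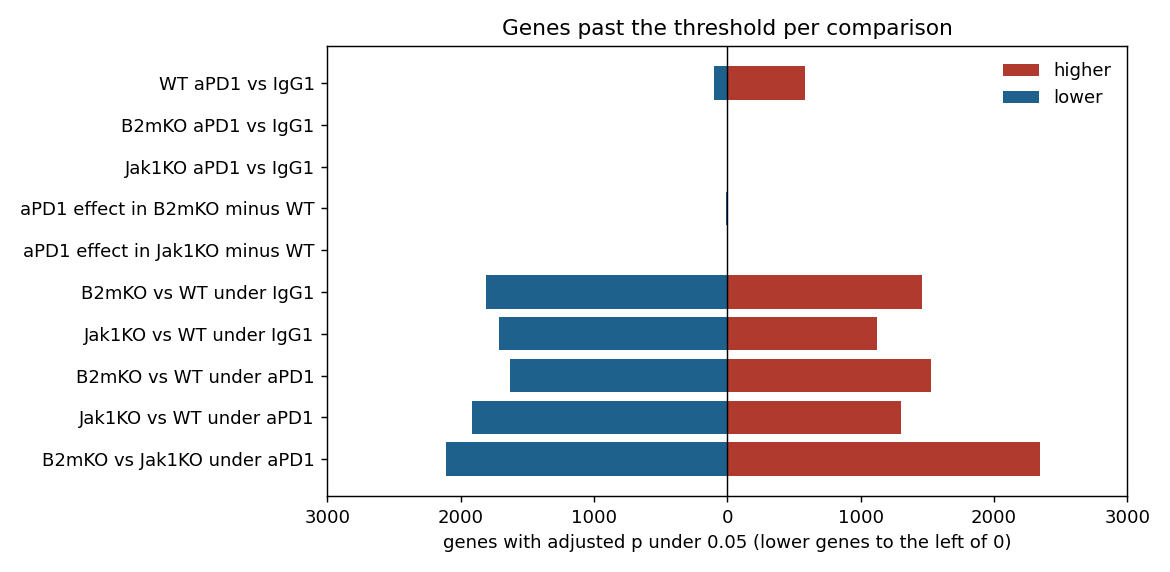
Number of genes with an adjusted p under 0.05 in each comparison (horizontal axis), higher in the first group to the right of 0 and lower to the left. In WT tumours 579 genes were higher and 100 lower with aPD1, and the comparisons between genotypes ranged from 2833 to 4461 genes.

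The first question was what aPD1 changed in WT tumours. Interferon gamma and its targets rose. Ifng, the cytokine itself, went from 0.262 ± 0.130 CPM with IgG1 to 3.93 ± 1.94 CPM with aPD1 (SD, n = 5; 3.91 ± 0.67, edgeR adjusted p = 0.00118). Ido1, an interferon-induced tryptophan-degrading enzyme (chromosome 8, 24584136 to 24597009), went from 0.364 ± 0.0859 CPM to between 1.22 and 4.57 CPM in the 5 libraries (3.14 ± 0.37, edgeR adjusted p = 7.58e-06, the smallest of all genes). Cd274, which encodes PD-L1, the ligand of PD-1 (chromosome 19, 29367455 to 29388095), went from 37.6 ± 9.98 to 146 ± 53.1 CPM (1.96 ± 0.29, edgeR adjusted p = 0.000951). In all, 679 genes passed the threshold, 579 higher and 100 lower.

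Of the 29 interferon gamma response genes, 25 rose and none fell (29 higher adjusted over the list alone), with Irgm1 at 1.03 ± 0.16 and Gbp7 at 1.17 ± 0.19, both GTPases of cell-autonomous immunity. The list mean was 6.98 ± 0.51 log2 CPM with aPD1 and 5.48 ± 0.46 with IgG1. The list's camera adjusted p was 7.24e-35, and adjusted p = 0.0749 with an estimated correlation. The guanylate-binding protein gene Gbp2b had the largest rise among genes at 5 CPM or more (4.4 ± 0.97, edgeR adjusted p = 0.00801). It was followed by Inpp5j (3.81 ± 0.60), the secreted nuclease gene Dnase1l3 (3.50 ± 0.58), Ly6i (2.99 ± 0.60), Ifitm1 (2.93 ± 0.50) and the MHC class II transactivator Ciita. Ciita went from 6.23 ± 2.71 to 45.9 ± 28.1 CPM (2.89 ± 0.67, edgeR adjusted p = 0.0122), and the class II invariant chain Cd74 rose by 2.80 ± 0.75. Without WT aPD1 replicate 2 both missed the threshold (edgeR adjusted p = 0.0551 for Ciita and 0.0967 for Cd74), and Cd74 also without WT aPD1 replicate 1 or 5 or WT IgG1 replicate 1, 2 or 5 (0.0555, 0.054, 0.0868, 0.0597 and 0.0773). Of 10 MHC class II genes, 5 rose (10 adjusted over the list alone; adjusted p = 0.229 with an estimated correlation for the list). Of 24 MHC class I genes, 7 rose (15 adjusted over the list alone; adjusted p = 0.197 with an estimated correlation). Among them were the peptide transporter genes Tap1 (0.96 ± 0.16) and Tap2 (0.55 ± 0.11) and the regulator Nlrc5 (1.48 ± 0.28). Of 24 type I interferon response genes, none passed over all genes or adjusted over the list alone. By exact permutation of list means no list passed for aPD1 in WT tumours (smallest adjusted p = 0.0742, reached by the interferon gamma list among others, with 16 lists at an unadjusted exact p under 0.05).

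Of 19 cytotoxic effector genes, 11 rose (15 adjusted over the list alone; adjusted p = 0.187 with an estimated correlation), with the receptor gene Klrk1 at 2.11 ± 0.47 and the transcription factor gene Tbx21 at 2.26 ± 0.53. Of 17 immune checkpoint and exhaustion genes, 10 rose (12 adjusted over the list alone; adjusted p = 0.134 with an estimated correlation): Pdcd1lg2, the other PD-1 ligand, by 3.43 ± 0.58, Entpd1 by 1.52 ± 0.28 and Havcr2 by 1.10 ± 0.25. Of 7 regulatory T cell genes, 5 rose (5 adjusted over the list alone; adjusted p = 0.0749 with an estimated correlation), with Ctla4 at 2.35 ± 0.56 and Foxp3 at 1.54 ± 0.40. Of 21 T cell genes, 3 rose (19 adjusted over the list alone; adjusted p = 0.229 with an estimated correlation), among them Trbc1 by 2.01 ± 0.51 and Cd2 by 1.84 ± 0.51. Without WT aPD1 replicate 2, Tbx21, Havcr2, Ctla4, Foxp3, Trbc1 and Cd2 missed the threshold (edgeR adjusted p from 0.0628 for Havcr2 to 0.123 for Cd2). Foxp3, Trbc1 and Cd2 also did without WT IgG1 replicate 1 (from 0.0686 for Trbc1 to 0.0913 for Cd2), Foxp3 and Cd2 also without WT aPD1 replicate 1 or 5, and Cd2 and Trbc1 also without WT IgG1 replicate 5. Clec9a, a marker of cross-presenting dendritic cells (2.2 ± 0.37), and the neutrophil receptor genes Clec4d (1.87 ± 0.34) and Csf3r (1.69 ± 0.33) rose as well. The largest falls among genes at 5 CPM or more were in Fcrls (-2.25 ± 0.48, edgeR adjusted p = 0.006), Mest (-1.82 ± 0.52), the endothelin receptor gene Ednrb (-1.66 ± 0.41), the oxysterol receptor gene Gpr183 (-1.45 ± 0.29) and the matrix genes Mfap4 (-1.19 ± 0.35) and Aspn (-1.17 ± 0.34). Mest, Ednrb, Mfap4 and Aspn missed the threshold without WT aPD1 replicate 1, 2 or 5 or WT IgG1 replicate 1 (edgeR adjusted p from 0.0534 for Ednrb to 0.144 for Mfap4).

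Of 139 protease genes in WT tumours, 8 rose and 2 fell with aPD1 (15 and 5 adjusted over the lists alone). Among all 15505 genes tested, 579 rose and 100 fell. Mmp25, a membrane-anchored matrix metalloproteinase gene known from neutrophils (chromosome 17, 23628311 to 23645277), went from 2.18 ± 0.933 to 9.22 ± 5.38 CPM (SD, n = 5; 2.08 ± 0.40, edgeR adjusted p = 0.00342). The granzyme genes Gzmb (8.57 ± 6.27 to 42.3 ± 17.7 CPM; 2.31 ± 0.61, edgeR adjusted p = 0.0268) and Gzma (1.67 ± 1.76 to 5.98 ± 3.11 CPM; 1.90 ± 0.54, edgeR adjusted p = 0.0414), serine proteases of killer lymphocyte granules, rose. Gzmk was at 2.92 ± 0.89 and did not pass (edgeR adjusted p = 0.0539). The lysosomal cathepsin genes Ctss (1.26 ± 0.31, edgeR adjusted p = 0.0167) and Ctsc, whose product activates granzymes (1.01 ± 0.26, edgeR adjusted p = 0.0216), the aminopeptidase gene Anpep (1.25 ± 0.27), the dipeptidyl peptidase gene Dpp4 (1.26 ± 0.36) and the sheddase gene Adam8 (0.76 ± 0.20) also rose. Prss23 (-0.53 ± 0.14, edgeR adjusted p = 0.0245) and the plasminogen activator gene Plat fell, Plat from 100 ± 31.5 to 68.2 ± 4.75 CPM (-0.55 ± 0.15, edgeR adjusted p = 0.0348). Without WT aPD1 replicate 2, Mmp25 and Anpep were past the threshold and the other 8 were not, with edgeR adjusted p from 0.0673 for Prss23 to 0.16 for Gzma. The same 8 missed it without WT IgG1 replicate 1 (0.0563 for Ctss to 0.129 for Gzma), and some of them without each other WT library except aPD1 replicate 4. The protease lists together had a camera adjusted p of 0.0212, and adjusted p = 0.375 with an estimated correlation. The macrophage and monocyte list mean was 7.24 ± 0.40 log2 CPM with aPD1 and 6.58 ± 0.59 with IgG1 (exact permutation adjusted p = 0.125).

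The WT count depended on single libraries. Without WT aPD1 replicates 1, 2, 4 and 5 it was 367, 230, 1107 and 388. Without WT IgG1 replicates 1 and 5 it was 349 and 377. In a fit of the WT groups alone it was 55, so the pooled fit's 679 may be too high. Of the 66 named genes past the threshold, 28 kept their call whichever library was left out, among them Ifng, Ido1, Cd274, Pdcd1lg2, Irgm1, Gbp7, Tap1, Nlrc5, Klrk1, Clec9a and Fcrls. The other 38 lost it without WT aPD1 replicate 2, the library whose header names an alignment file other than its own. The protease count rose to 18 when WT IgG1 replicate 3 and B2mKO aPD1 replicate 2, which stand apart from the other libraries, were left out (8 of the 18 are among the 10), and fell to 3 without a filter beyond 1 count and to 1 in the fit of the WT groups alone.

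**Figure D3:**
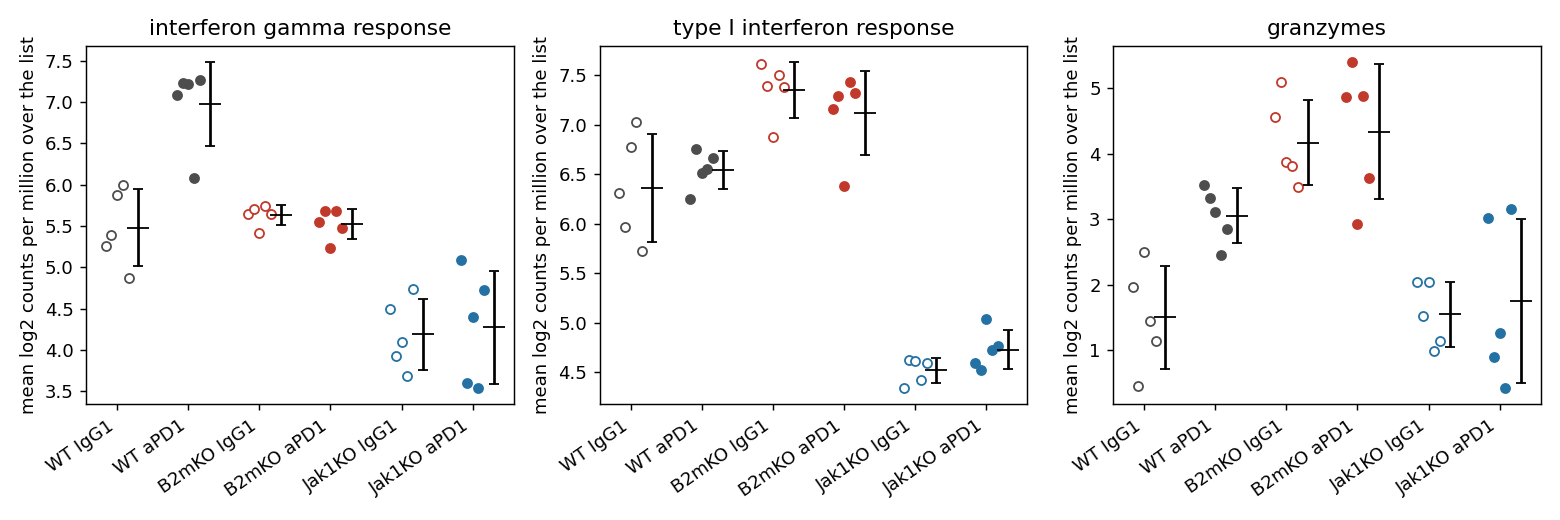
Mean log2 CPM over the interferon gamma response, type I interferon response and granzyme lists in each library; open circles are IgG1, filled circles aPD1, and the line and bars the group mean ± SD (n = 5). The WT aPD1 libraries lie between 6.08 and 7.27 on the interferon gamma list, and the Jak1KO libraries lie lowest on the type I interferon list.

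**Figure D4:**
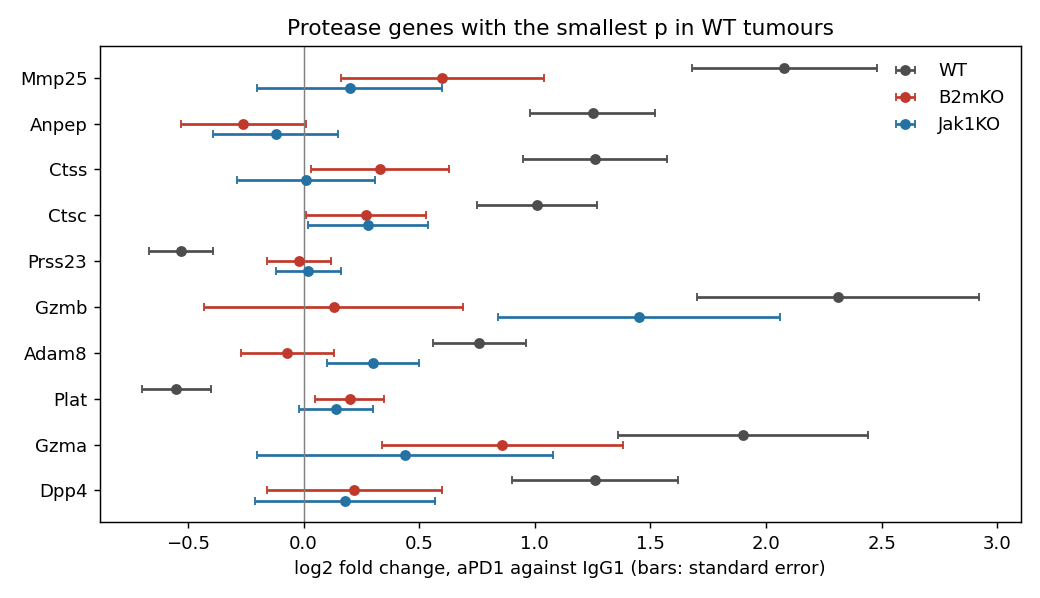
Log2 fold change of aPD1 against IgG1 (horizontal axis) with its standard error for the 10 protease genes with the smallest p in WT tumours, shown for WT, B2mKO and Jak1KO tumours. In WT tumours Mmp25 is at 2.08 and Gzmb at 2.31, and none of the 10 genes passed the threshold in either knockout.

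The same treatment was then compared within B2mKO tumours. Ifng was at 0.0708 ± 0.0598 CPM with IgG1 and 0.183 ± 0.193 CPM with aPD1 (SD, n = 5), Cd274 at 49.7 ± 14.2 and 42.1 ± 9.51 CPM, and Gzmb at 47.1 ± 28.4 and 51.7 ± 26.8 CPM. No gene passed edgeR's threshold (smallest adjusted p = 0.801), 511 genes had an unadjusted p under 0.05, and DESeq2 and limma voom also called 0. The genes with the smallest p were Hoxb7 (1.73 ± 0.38), Nab1 (-0.29 ± 0.08), Ccdc125 (0.88 ± 0.23), Rwdd2a (0.79 ± 0.21), Lrrtm2 (-0.52 ± 0.15) and B3galnt1 (0.87 ± 0.25). B2m was at 0.28 ± 0.19 and Jak1 at -0.12 ± 0.10.

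Small shifts shared by the members of a list, none past the threshold by itself or adjusted over its list alone, gave camera calls for 13 lists in B2mKO tumours (10 higher, 3 lower). T cell genes had a median change of 0.588 (camera adjusted p = 0.000108), macrophage and monocyte genes of 0.282 and MHC class II genes of 0.617. Type I interferon response genes had a median of -0.187 (camera adjusted p = 0.00095), with Oas3 at -0.67 ± 0.29 and Oas2 at -0.66 ± 0.31. Mitochondrially encoded genes (-0.303) and collagens (-0.151) were the other lower lists. Cathepsins (0.227), coagulation and complement proteases (0.185), cytotoxic genes (0.369) and proteasome genes (0.181) were among the higher ones. For all 13, adjusted p = 0.718 with an estimated correlation, and no list passed by fry (adjusted p = 0.721) or by exact permutation of list means. Among proteases the smallest p belonged to Adamts12 (-0.56 ± 0.23), Ctsf (0.82 ± 0.35) and Gzmk (1.45 ± 0.62), and 0 of 139 passed. Without B2mKO aPD1 replicate 2 the list count was 5 and the mean of the proteasome list was -0.05, in the other direction. Without B2mKO IgG1 replicate 1 the list count was 6.

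In Jak1KO tumours Ifng was at 0.865 ± 0.770 CPM with IgG1 and 1.24 ± 1.32 CPM with aPD1 (SD, n = 5), Cd274 at 26.2 ± 4.34 and 28.5 ± 13.3 CPM, and Gzmb at 6.21 ± 1.88 and 16.9 ± 17.0 CPM (1.45 ± 0.61, edgeR adjusted p = 1). No gene passed edgeR's threshold (smallest adjusted p = 1), 172 had an unadjusted p under 0.05, and DESeq2 and limma voom also called 0. The smallest p values were those of Arhgap8 (1.64 ± 0.46), Tnfsf18, which encodes the ligand of the co-stimulatory receptor GITR (1.61 ± 0.47), Prokr1 (0.84 ± 0.26), Tmem156 (0.88 ± 0.27), Mreg (0.74 ± 0.23) and Heatr9 (0.92 ± 0.29). B2m was at 0.05 ± 0.19 and Jak1 at 0.02 ± 0.10.

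Camera called 9 lists in this comparison (5 higher, 4 lower). Several mark other tissues. Skeletal muscle genes had a median of 2.454, with Myoz1 at 2.10 ± 0.79 and Ckm at 3.23 ± 1.48. Adipocyte genes had a median of -0.603, with Adipoq at -2.73 ± 1.07 and the complement protease gene Cfd at -3.59 ± 1.22 (2 members lower adjusted over the list alone). Simple epithelial genes had a median of -1.748, with Epcam at -2.46 ± 1.03 (4 lower adjusted over the list alone). The epithelial counts were low: Krt18 held 76 counts with IgG1 and 3 with aPD1 (ratio 26.5, counting interval 8.74 to 131) and Krt8 85 and 2 (44.5, 11.9 to 373). The muscle list mean was -0.40 ± 2.03 log2 CPM with IgG1 and 1.68 ± 2.54 with aPD1. Type I interferon response genes had a median of 0.214 (camera adjusted p = 1.08e-06; Oasl1 at 0.37 ± 0.21) and unfolded protein response genes of 0.106 (Creld2 at 0.11 ± 0.08). T cell genes were called lower by camera (adjusted p = 0.0129) although their median (0.025) and mean (0.029) lay above 0. With an estimated correlation adjusted p = 0.325 or more for all 9, fry called none (adjusted p = 0.979) and the exact permutation of list means called none. Without Jak1KO aPD1 replicate 4 the list count was 14, and the checkpoint list, called lower, had a mean of -0.022 with camera's direction turned. Without Jak1KO IgG1 replicate 2 the list count was 15.

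Whether the aPD1 effect differed between B2mKO and WT tumours was tested directly. For Cd274 the aPD1 effect was lower in B2mKO tumours by -2.2 ± 0.40 (edgeR adjusted p = 0.0234), for Gbp7 by -1.5 ± 0.26 (edgeR adjusted p = 0.0203), and for Il2rg, the common cytokine receptor chain, by -1.74 ± 0.32 (edgeR adjusted p = 0.0234). Il2rg was at 20.0 ± 4.77 and 53.2 ± 16.4 CPM in WT and at 38.0 ± 5.99 and 30.3 ± 4.59 CPM in B2mKO tumours with IgG1 and aPD1 (SD, n = 5). The difference passed for 15 genes, 13 lower and 2 higher, and 2550 genes had an unadjusted p under 0.05. Lrrtm2, a synaptic adhesion gene (-1.29 ± 0.21), and the transcriptional co-repressor gene Nab1 (-0.57 ± 0.11) were lower and the potassium channel subunit gene Kcne3 (3.33 ± 0.58) was higher, from -2.46 in WT to 0.87 in B2mKO tumours.

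Of the 29 interferon gamma response genes, 4 passed this test, all lower in B2mKO tumours (27 adjusted over the list alone), among them Irgm1 (-1.21 ± 0.23) and Gbp4 (-1.70 ± 0.34). The list's camera adjusted p was 2.41e-25, and adjusted p = 0.469 with an estimated correlation. Of MHC class I genes, Tap2 passed (-0.75 ± 0.15, edgeR adjusted p = 0.0333; 8 lower adjusted over the list alone; adjusted p = 0.646 with an estimated correlation for the list), and Tap1 (-1.01 ± 0.22) and Nlrc5 (-1.74 ± 0.39) did not. Camera called 13 lists lower and 2 higher, none of which it called with an estimated correlation (adjusted p = 0.469 or more), and fry called 3. No protease gene passed by edgeR and 1 passed by DESeq2. The smallest p values were those of Anpep (-1.51 ± 0.38), Prss46 (-2.59 ± 0.75), Plat (0.76 ± 0.22) and Erap1, which trims peptides for MHC class I (-0.35 ± 0.12), and Gzmb was at -2.17 ± 0.82. The count of 15 fell to 0 without WT aPD1 replicate 2 or 5 or WT IgG1 replicate 1, and was 1 without WT aPD1 replicate 1, 9 without replicate 3 and 154 without replicate 4. Without WT IgG1 replicates 3, 4 and 5 in turn it was 7, 158 and 2. Without B2mKO aPD1 replicates 1, 2 and 3 it was 23, 4 and 3, and without B2mKO IgG1 replicates 2, 4 and 5 it was 9, 4 and 9. Without WT aPD1 replicate 2 the edgeR adjusted p was 0.0875 for Irgm1 and 0.0937 for Gbp4 and Tap2, and none of the 9 named genes kept its call.

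Between Jak1KO and WT tumours no difference in the aPD1 effect passed edgeR's threshold (smallest adjusted p = 0.194). There were 1279 genes with an unadjusted p under 0.05, limma voom called 0 and DESeq2 called 51. The 6 genes with the smallest p were Gbp7 (-1.26 ± 0.26), Gpr132 (-1.91 ± 0.40), Tent5c (-1.22 ± 0.26), Cd274 (-1.84 ± 0.40), Ttc39b (-0.55 ± 0.12) and Tnfrsf14 (-0.95 ± 0.21). Adjusted over the list alone, 26 of 29 interferon gamma response genes, 11 of 17 checkpoint genes and 5 of 7 regulatory T cell genes were lower, among them Irgm1 (-1.02 ± 0.23), Irf1 (-0.78 ± 0.19), Pdcd1lg2 (-3.68 ± 0.88) and Ctla4 (-2.43 ± 0.78). For each of these 3 lists adjusted p = 0.0893 with an estimated correlation and fry's adjusted p was 0.0187. Camera called 15 lists lower and 2 higher, the skeletal muscle and unfolded protein response lists, and none with an estimated correlation (adjusted p = 0.0893 or more). Of the 139 proteases, none passed. Anpep was at -1.37 ± 0.38, Mmp25 at -1.88 ± 0.57, Ctss at -1.26 ± 0.43, Plat at 0.70 ± 0.22 and Plau, another plasminogen activator gene, at 0.84 ± 0.29. The count was 128 without WT aPD1 replicate 4 and 10 without WT IgG1 replicate 4.

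B2mKO and WT tumours were compared under IgG1, to see how the lines differed without checkpoint blockade. Members of the granzyme and matrix lists were higher in B2mKO tumours and members of the proliferation list lower. Gzmf, a granzyme gene of the chromosome 14 cluster (56205263 to 56211417), was at 5.87 ± 4.02 CPM in WT and 126 ± 107 CPM in B2mKO tumours (SD, n = 5; 4.42 ± 0.85, edgeR adjusted p = 0.000525). Fap, the fibroblast activation protein gene (chromosome 2, 62500943 to 62574075), was at 4.00 ± 1.22 and 18.2 ± 6.45 CPM (2.18 ± 0.33, edgeR adjusted p = 2.3e-05). In all, 1457 genes were higher and 1813 lower. Hpse2, a heparanase-family gene (chromosome 19, 42786539 to 43388355), held 554 counts in B2mKO and 3 in WT tumours (ratio 174, counting interval 59.2 to 845). Tmprss11g, a transmembrane serine protease gene (chromosome 5, 86485876 to 86518600), held none in B2mKO and 552 in WT tumours, at least 196-fold lower by a floor of 3 counts over the group (the exact counting interval starts at 158). Other large rises were in the desmosomal cadherin gene Dsc2 (5.68 ± 0.81), the prostaglandin F receptor gene Ptgfr (4.74 ± 0.62), Inmt (4.49 ± 0.53) and Fcrl6 (4.47 ± 0.76). Other large falls were in the muscarinic receptor gene Chrm3 (-5.90 ± 0.47), the slow myosin gene Myh7 (-5.52 ± 1.42), Bnc1 (-4.70 ± 0.42), Sntb1 (-3.69 ± 0.24) and Bhlhe22 (-3.66 ± 0.31). Without WT IgG1 replicate 2 the change of Myh7 was -1.02 (edgeR adjusted p = 0.672).

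Of 9 granzyme genes, 6 were higher in B2mKO tumours (6 adjusted over the list alone; camera adjusted p = 0.000152, and adjusted p = 0.474 with an estimated correlation). Gzmc was higher by 3.11 ± 0.52, Gzmd by 4.03 ± 0.79, Gzme by 3.91 ± 0.76 and Gzmb by 2.46 ± 0.61, and so was the pore-forming protein gene Prf1 (3.38 ± 0.59, edgeR adjusted p = 0.000167). These genes lie in clusters of close copies, so how reads divide among Gzmc to Gzmf is uncertain. Of 12 NK cell genes, 8 were higher and 1 lower (the same counts adjusted over the list alone; adjusted p = 0.619 with an estimated correlation), with Klra7 at 2.87 ± 0.57, Il2rb at 2.24 ± 0.43 and Ncr1 at 2.33 ± 0.51. Of 31 collagen and matrix genes, 17 were higher (18 adjusted over the list alone; adjusted p = 0.474 with an estimated correlation), such as Lum (2.03 ± 0.39), Col5a2 (1.46 ± 0.27) and Col8a1 (1.13 ± 0.11). Of 18 TGF-beta target genes, 11 were higher (11 adjusted over the list alone, with 1 lower; adjusted p = 0.0627 with an estimated correlation), such as Skil (0.51 ± 0.08) and Tgfb3 (1.29 ± 0.22). Of 24 type I interferon response genes, 17 were higher (22 adjusted over the list alone; adjusted p = 0.474 with an estimated correlation), among them the RNA sensor gene Ifih1 (0.97 ± 0.14) and Oasl1 (1.23 ± 0.20). Of 25 proliferation genes, 16 were lower (18 adjusted over the list alone; adjusted p = 0.497 with an estimated correlation), among them Bub1 (-0.68 ± 0.10), Top2a (-0.58 ± 0.10) and Mcm5 (-0.71 ± 0.14). The mitochondrially encoded genes mt-Nd2 (0.78 ± 0.21) and mt-Co1 (0.66 ± 0.18) were higher. By exact permutation of list means no list passed (15 lists at an unadjusted exact p under 0.05). The adjusted p was 0.0556 for the granzyme, collagen and TGF-beta lists, among the 6 at the smallest p the test can give, 0.0742 for the NK cell and type I interferon lists and 0.0909 for proliferation. The skeletal muscle list mean, which differs widely within groups, was -0.33 ± 2.18 log2 CPM in B2mKO and 1.85 ± 1.88 in WT tumours.

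Among the 139 protease genes, 22 were higher and 8 lower in B2mKO tumours under IgG1 (23 and 8 adjusted over the lists alone). Of all 15505 genes tested, 1457 were higher and 1813 lower, so protease genes passed about as often as any gene. Adamts8, a metalloprotease gene (chromosome 9, 30942562 to 30963838), was at 7.92 ± 2.26 CPM in WT and 1.34 ± 0.496 CPM in B2mKO tumours (SD, n = 5; -2.55 ± 0.22, edgeR adjusted p = 1.28e-09). Bmp1, the procollagen-processing protease gene (0.79 ± 0.10), the gelatinase gene Mmp9 (1.08 ± 0.19), Tmprss6 (3.39 ± 0.63) and Erap1 (0.44 ± 0.08) were higher, as was the cathepsin G gene Ctsg, from 0.0533 ± 0.0913 to 2.97 ± 2.86 CPM (5.53 ± 0.97, edgeR adjusted p = 8.1e-05). The protease lists together did not pass by camera (adjusted p = 0.182), while their mean was 4.25 ± 0.09 log2 CPM in B2mKO and 4.06 ± 0.10 in WT tumours (exact permutation p = 0.0238, not adjusted). Of the 66 named genes past the threshold, 57 kept their call whichever library was left out, and 5 of the other 9 were lost without B2mKO IgG1 replicate 5. In a fit of these 2 groups alone, 1444 genes passed.

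Jak1KO and WT tumours under IgG1 differed first in interferon-induced genes. All 24 type I interferon response genes were lower in Jak1KO tumours (24 adjusted over the list alone), by -2.96 ± 0.23 for Ifit1 (edgeR adjusted p = 2.17e-10), -3.30 ± 0.31 for Ifi44 and -2.57 ± 0.23 for Cmpk2. The list mean was 4.52 ± 0.13 log2 CPM in Jak1KO and 6.36 ± 0.54 in WT tumours (SD, n = 5). Ifit3b was at -3.18 ± 0.30 and shares sequence with Ifit3. For this list the exact permutation adjusted p was 0.0476, and adjusted p = 0.123 with an estimated correlation in camera. Of 29 interferon gamma response genes, 21 were lower (23 adjusted over the list alone; adjusted p = 0.468 with an estimated correlation; exact permutation adjusted p = 0.0476), including Irgm2 (-2.46 ± 0.26), Gbp3 (-2.40 ± 0.27), Gbp7 (-1.68 ± 0.19) and Igtp (-2.51 ± 0.30). In all, 1121 genes were higher and 1712 lower.

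Of 24 MHC class I genes, 15 were lower in Jak1KO tumours (17 adjusted over the list alone; adjusted p = 0.375 with an estimated correlation; exact permutation adjusted p = 0.0476), among them H2-Q6 (-2.53 ± 0.22), H2-Q7 (-2.16 ± 0.22) and H2-Q4 (-1.27 ± 0.15), 3 related genes whose reads may be divided unevenly. The interferon signalling genes Irf9 (-1.51 ± 0.17) and Stat2 (-1.63 ± 0.19) were lower. So were 9 of 15 unfolded protein response genes (12 adjusted over the list alone; adjusted p = 0.123 with an estimated correlation; exact permutation adjusted p = 0.0476), such as Herpud1 (-0.78 ± 0.12) and Xbp1 (-0.53 ± 0.11). Of 21 T cell genes, 7 were higher (13 adjusted over the list alone; adjusted p = 0.919 with an estimated correlation; exact permutation adjusted p = 0.0742), with Cd4 at 1.74 ± 0.36. Hpse2 was again higher, with 1408 counts against 3 in WT tumours (ratio 455, counting interval 155 to 2210). Also higher were the matrix genes Lama2 (3.41 ± 0.55), Eln, which encodes elastin (2.95 ± 0.60), and Mfap2 (2.80 ± 0.52), with Pnma5 (2.88 ± 0.31). Strc, the stereocilin gene (chromosome 2, 121363728 to 121387168), held 1 count in Jak1KO and 1231 in WT tumours (lower by a ratio of 1270, counting interval 227 to 50200). Myh7 (-7.11 ± 1.72), Cdh10 (-7.05 ± 0.49), Tex13b (-6.11 ± 0.51), Glrb (-5.68 ± 0.40) and Aif1l (-5.23 ± 0.48) were also lower. Without WT IgG1 replicate 2 the change of Myh7 was -2.60 (edgeR adjusted p = 0.372).

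Among the 139 protease genes 10 were higher and 24 lower in Jak1KO tumours under IgG1 (13 and 27 adjusted over the lists alone). This stands beside 1121 higher and 1712 lower of all 15505 genes tested. Casp1, the inflammasome caspase gene (chromosome 9, 5298508 to 5307290), was at 97.6 ± 35.5 CPM in WT and 20.3 ± 3.12 CPM in Jak1KO tumours (SD, n = 5; -2.26 ± 0.20, edgeR adjusted p = 3.04e-09). Of 9 caspase genes, 4 were lower (4 adjusted over the list alone; adjusted p = 0.762 with an estimated correlation; exact permutation adjusted p = 0.0476), Casp4 by -1.44 ± 0.18 and Casp12 by -1.04 ± 0.16. The immunoproteasome subunit gene Psmb9 (-1.51 ± 0.28) and Psmb8 (-0.88 ± 0.17), Adamts8 (-3.54 ± 0.24, at 0.688 ± 0.217 CPM), Mmp28 (-2.86 ± 0.35), Ctso (-1.02 ± 0.18) and Plat (-1.32 ± 0.16, at 40.2 ± 4.10 CPM) were lower, and Nln (0.67 ± 0.10) and Adamts1 (1.34 ± 0.21) higher. Of the 54 named genes past the threshold, 44 kept their call whichever library was left out, and 8 of the other 10 were lost without WT IgG1 replicate 3. In a fit of these 2 groups alone, 1641 genes passed.

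Under aPD1, B2mKO tumours differed from WT tumours in interferon gamma targets and in collagen and matrix genes. Ido1 was between 1.22 and 4.57 CPM in WT and at 0.126 ± 0.153 CPM in B2mKO tumours (SD, n = 5; -4.62 ± 0.45, edgeR adjusted p = 1.62e-09). Cd274 was at 146 ± 53.1 and 42.1 ± 9.51 CPM (-1.80 ± 0.29, edgeR adjusted p = 4.74e-05). Fap was at 1.93 ± 0.744 and 21.2 ± 11.9 CPM (3.45 ± 0.35, edgeR adjusted p = 3.84e-08). In all, 1529 genes were higher and 1629 lower. Of 29 interferon gamma response genes, 26 were lower (27 adjusted over the list alone; adjusted p = 0.49 with an estimated correlation), with Tgtp1 at -3.03 ± 0.42 and Gbp4 at -1.56 ± 0.25. Of 10 MHC class II genes, 8 were lower (10 adjusted over the list alone; adjusted p = 0.714 with an estimated correlation), with Ciita at -3.74 ± 0.71 and Cd74 at -3.70 ± 0.78. Of 24 type I interferon response genes, 9 were higher (13 adjusted over the list alone; adjusted p = 0.741 with an estimated correlation), such as Ifih1 (0.71 ± 0.14) and Usp18 (1.38 ± 0.28). No list passed in this comparison by exact permutation of list means (smallest adjusted p = 0.111, with 15 lists at an unadjusted exact p under 0.05).

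Of 31 collagen and matrix genes, 18 were higher in B2mKO tumours under aPD1 (19 adjusted over the list alone; adjusted p = 0.614 with an estimated correlation), with Lum at 3.59 ± 0.42 and Postn at 1.95 ± 0.29. Of 17 endothelial genes, 9 were higher (12 adjusted over the list alone; adjusted p = 0.741 with an estimated correlation), with the tight junction gene Cldn5 at 1.36 ± 0.32 and the angiopoietin receptor gene Tek at 1.82 ± 0.46. The largest rises were in Hpse2 (682 counts against 2, ratio 357, counting interval 98.5 to 2960), Mfap4 (4.84 ± 0.39), Inmt (4.77 ± 0.50), Dppa4 (4.44 ± 0.33), Ptgfr (4.09 ± 0.60) and Vstm5 (3.95 ± 0.31). The largest falls were in Chrm3 (-7.64 ± 0.50), Gbp2b (-7.51 ± 1.23), Bnc1 (-5.96 ± 0.47), Dnase1l3 (-4.76 ± 0.64), Inpp5j (-4.34 ± 0.64) and Sntb1 (-4.03 ± 0.25). Of 139 protease genes, 24 were higher and 14 lower (25 and 20 adjusted over the lists alone), beside 1529 and 1629 of all 15505 genes. The mean over the protease lists together was 4.34 ± 0.21 log2 CPM in B2mKO and 4.33 ± 0.13 in WT tumours (exact permutation p = 0.944, not adjusted). Bmp1 (0.93 ± 0.10), Mmp9 (1.17 ± 0.19), Ctso (1.01 ± 0.18), Plat (0.78 ± 0.15), Plau (0.86 ± 0.20), the complement protease gene Masp1 (1.71 ± 0.36) and Ctsg (3.40 ± 0.74) were higher, and Adamts8 (-2.74 ± 0.22), Adam8 (-1.06 ± 0.20) and Adam9 (-0.38 ± 0.08) lower. Of the 61 named genes past the threshold, 58 kept their call whichever library was left out, and the other 3 were lost without B2mKO aPD1 replicate 1. Over all genes, 1780 passed in a fit of these 2 groups alone.

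Under aPD1, all 29 interferon gamma response genes were lower in Jak1KO than in WT tumours (29 adjusted over the list alone; adjusted p = 0.0694 with an estimated correlation; exact permutation adjusted p = 0.0303), Gbp7 by -2.94 ± 0.20 (edgeR adjusted p = 1.55e-11), Irgm1 by -2.17 ± 0.17 and Gbp3 by -3.50 ± 0.28. The list mean was 4.27 ± 0.69 log2 CPM in Jak1KO and 6.98 ± 0.51 in WT tumours (SD, n = 5). Cd274 was at 28.5 ± 13.3 and 146 ± 53.1 CPM (-2.36 ± 0.29, edgeR adjusted p = 8.23e-07). In all, 1303 genes were higher and 1918 lower. Of 24 type I interferon response genes, 23 were lower (23 adjusted over the list alone), such as Ifit1 (-2.72 ± 0.23) and Zbp1 (-2.44 ± 0.22). Of 24 MHC class I genes, 20 were lower (21 adjusted over the list alone), such as H2-Q6 (-3.16 ± 0.23) and Tap1 (-1.89 ± 0.16). For both lists adjusted p = 0.0694 with an estimated correlation and the exact permutation adjusted p was 0.0303.

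All 10 MHC class II genes were lower in Jak1KO tumours (10 adjusted over the list alone; adjusted p = 0.454 with an estimated correlation; exact permutation adjusted p = 0.0666), such as Cd74 (-2.55 ± 0.74). So were 7 of 12 neutrophil genes (8 adjusted over the list alone; adjusted p = 0.182 with an estimated correlation; exact permutation adjusted p = 0.0303), such as the receptor genes Trem1 (-1.89 ± 0.27) and Il1r2 (-1.90 ± 0.36). The chemokine genes Cxcl10 (-1.96 ± 0.20) and Ccl5 (-1.61 ± 0.33), the cytotoxic genes Gzma (-1.97 ± 0.54) and Klrk1 (-1.59 ± 0.45), and Ifng (-1.62 ± 0.50) were lower. Ifng missed the threshold without WT aPD1 replicate 3 or Jak1KO aPD1 replicates 2, 3 or 4 (edgeR adjusted p = 0.0523, 0.0597, 0.0522 and 0.0607). Among the largest rises were Hpse2 (1520 counts against 2, ratio 745, counting interval 206 to 6150), Lama2 (4.63 ± 0.59), Eln (4.56 ± 0.64), Mfap4 (4.18 ± 0.38) and Mfap2 (3.79 ± 0.52). The largest falls were in Strc (1 count against 1603, lower by a ratio of 1640, counting interval 293 to 64700), Apol6 (-5.06 ± 0.44), Krt16 (-5.05 ± 0.61), Tex13b (-5.01 ± 0.48), Glrb (-4.89 ± 0.37) and Gbp10 (-4.63 ± 0.49). Of 139 protease genes, 9 were higher and 39 lower (11 and 44 adjusted over the lists alone; camera adjusted p = 0.00191, and adjusted p = 0.264 with an estimated correlation). The counts over all 15505 genes were 1303 higher and 1918 lower. Casp1 was at 132 ± 17.1 CPM in WT and 21.5 ± 4.65 CPM in Jak1KO tumours (-2.62 ± 0.20). Casp4 (-1.76 ± 0.18), Mmp28 (-2.99 ± 0.32), Psmb9 (-2.24 ± 0.28), Psmb8 (-1.17 ± 0.18), Adam8 (-1.30 ± 0.20) and Adamts8 (-3.03 ± 0.23) were lower. So were 8 of 14 cathepsin genes (8 adjusted over the list alone; adjusted p = 0.536 with an estimated correlation; exact permutation adjusted p = 0.0666), with Ctss at -1.20 ± 0.31. The macrophage and monocyte list mean was 6.75 ± 0.25 log2 CPM in Jak1KO and 7.24 ± 0.40 in WT tumours (exact permutation adjusted p = 0.106). Prss23 (1.08 ± 0.14), Adamts1 (1.44 ± 0.22) and Nln (0.63 ± 0.10) were higher. Of the 79 named genes past the threshold, 70 kept their call whichever library was left out, and 7 of the other 9 were lost without Jak1KO aPD1 replicate 3. Without WT IgG1 replicate 3 and B2mKO aPD1 replicate 2 the count was 5236.

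The last comparison set B2mKO against Jak1KO tumours under aPD1. All 24 type I interferon response genes were higher in B2mKO tumours (24 adjusted over the list alone; adjusted p = 0.0633 with an estimated correlation; exact permutation adjusted p = 0.0417), such as Ifih1 (2.10 ± 0.14, edgeR adjusted p = 6.84e-12), Ifit1 (2.98 ± 0.23) and Ifi44 (3.89 ± 0.32). The list mean was 7.11 ± 0.42 log2 CPM in B2mKO and 4.73 ± 0.20 in Jak1KO tumours (SD, n = 5). In all, 2348 genes were higher and 2113 lower. B2m was lower (-0.74 ± 0.19, edgeR adjusted p = 0.00335) and Jak1 higher (1.94 ± 0.10, edgeR adjusted p = 9.19e-14). Of 24 MHC class I genes, 20 were higher and 1 lower (the same counts adjusted over the list alone; adjusted p = 0.275 with an estimated correlation; exact permutation adjusted p = 0.0417), with H2-K1 at 1.32 ± 0.18. Of 29 interferon gamma response genes, 20 were higher (20, with 2 lower, adjusted over the list alone; adjusted p = 0.398 with an estimated correlation; exact permutation adjusted p = 0.0417), with Gbp3 at 3.01 ± 0.27 and Gbp9 at 1.92 ± 0.17. Ifng itself was lower (-2.75 ± 0.81, edgeR adjusted p = 0.0104), and without Jak1KO aPD1 replicate 1 it was at -2.03 and missed the threshold (edgeR adjusted p = 0.0745).

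The list of 18 TGF-beta target genes had 11 higher and 1 lower member in B2mKO tumours (12 and 1 adjusted over the list alone), Id3 by 1.85 ± 0.24, Smad7 by 0.90 ± 0.12 and Skil by 0.65 ± 0.08. It was the only list over all comparisons that camera called with an estimated correlation (adjusted p = 0.0277; exact permutation adjusted p = 0.0417). Of 9 granzyme genes, 7 were higher (7 adjusted over the list alone; adjusted p = 0.398 with an estimated correlation; exact permutation adjusted p = 0.0769), Gzmd by 3.83 ± 0.78, Gzme by 3.57 ± 0.74 and Gzmf by 3.86 ± 0.82. Gzmf went from 9.04 ± 10.8 CPM in Jak1KO to 132 ± 108 CPM in B2mKO tumours. Of 25 proliferation genes, 15 were lower (17 adjusted over the list alone; adjusted p = 0.433 with an estimated correlation; exact permutation adjusted p = 0.0417), among them the replication genes Mcm3 (-0.76 ± 0.12) and Mcm4 (-0.74 ± 0.12). The largest rises were in Vstm5 (7.81 ± 0.47), Inmt (5.68 ± 0.55), Glrb (5.61 ± 0.36), Olfr810 (5.54 ± 0.62), Pde1a (4.92 ± 0.24) and Cdh19 (4.71 ± 0.31). The largest falls were in Olfr139 and Tmprss11g, with no counts in B2mKO and 813 and 628 in Jak1KO tumours (at least 253-fold and 196-fold lower by a floor of 3 counts over the group, with exact counting intervals that start at 206 and 159), Fndc3c1 (-6.84 ± 0.44), Bnc1 (-6.60 ± 0.45), the fast myosin gene Myh4 (-5.57 ± 2.00) and Gbp2b (-4.33 ± 1.24). Without Jak1KO aPD1 replicate 1 the edgeR adjusted p was 0.724 for Myh4 and 0.188 for Gbp2b, and Myh4 also missed the threshold without B2mKO aPD1 replicates 1, 2, 4 or 5 (0.0754, 0.0792, 0.0716 and 0.0768).

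Of the 139 protease genes, 45 were higher and 14 lower in B2mKO than in Jak1KO tumours under aPD1 (48 and 14 adjusted over the lists alone; camera adjusted p = 0.000626, and adjusted p = 0.275 with an estimated correlation). The counts over all 15505 genes were 2348 higher and 2113 lower. Casp1 (1.89 ± 0.20), Plat (1.40 ± 0.16, 117 ± 29.1 against 44.4 ± 4.46 CPM; SD, n = 5), Ctso (1.58 ± 0.19), Mmp28 (2.59 ± 0.33), Fap (2.39 ± 0.32), Bmp1 (0.76 ± 0.10), the complement protease genes C1ra (1.85 ± 0.26) and C1s1 (1.84 ± 0.36), and Erap1 (0.54 ± 0.08) were higher. Adamts1 (-1.51 ± 0.22), Nln (-0.63 ± 0.10) and Prss23 (-0.55 ± 0.14) were lower. The macrophage and monocyte list mean was 7.20 ± 0.15 log2 CPM in B2mKO and 6.75 ± 0.25 in Jak1KO tumours (exact permutation p = 0.0159, adjusted 0.0607). The inhibitor genes Timp1 (1.07 ± 0.14) and Reck (0.85 ± 0.14) were also higher. Of the 98 named genes past the threshold, 86 kept their call whichever library was left out, and 7 of the other 12 were lost without B2mKO aPD1 replicate 2.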

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

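The tests of transcript length and of RNA from other cells were chosen only after the result was seen, while the test of GC content was planned before the data were examined.

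In 162 groups of 5 libraries, the library farthest from the others was compared with them by Dixon's ratio of its gap to the group's range (critical value 0.71). In 11 groups it lay beyond that value, where chance gives about 1 in 20, or 8.1. Of 24 groups of library measures 1 was among them: the share of counts in the top 10 genes was 4.82% in B2mKO aPD1 replicate 2 and 7.03 to 7.77% in the other 4. In the same library Ido1 was at 0.392 CPM (others 0 to 0.0976) and Plat at 168 CPM (others 97.4 to 110). In WT IgG1 replicate 3, Jak1 was at 182 CPM (others 239 to 255) and Gzmb at 19.3 CPM (others 3.6 to 8). Gzmf was at 28.2 CPM in WT aPD1 replicate 1 (others 13.9 to 17.5), and Ctsg at 0.211 CPM in WT IgG1 replicate 1 (others 0 to 0.0556). The mean of the interferon gamma list was 6.08 log2 CPM in WT aPD1 replicate 4 (others 7.09 to 7.27), and that of the type I interferon list 6.38 in B2mKO aPD1 replicate 3 (others 7.16 to 7.43). The skeletal muscle list mean was 3.52 in B2mKO IgG1 replicate 5 (others -1.77 to -0.76) and 3.19 in Jak1KO IgG1 replicate 3 (others -1.5 to -0.84).

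WT IgG1 replicate 3 and B2mKO aPD1 replicate 2, which hold 5 of these 11 values, also departed from their group means in a similar way: across genes, which are not independent replicates, their deviations had a correlation of 0.75, against -0.59 to 0.62 in 326 pairs of the other 28 libraries from different groups. A trend with transcript length may contribute (rank correlation of deviation with length -0.365 and -0.437, others -0.296 to 0.364), but the pair's correlation was 0.71 with the trend removed, which argues against length as the whole cause. GC content had a rank correlation of -0.115 in B2mKO aPD1 replicate 2 and -0.208 in WT IgG1 replicate 3 (others -0.198 to 0.182), which argues against it for the first of these. RNA from cells of another type stays open, since the largest deviation that both reached on a cell type list was 0.84 log2, with an SD of 0.63 on that list in the other libraries. The 2 libraries carry the provider's numbers 8 and 9. They had 20466 and 21147 genes detected, fewer than any other library (next lowest 21594, in WT aPD1 replicate 3). Mitochondrial genes held 0.89% and 1.09% of their counts, with 0.99% in WT aPD1 replicate 3. Shared handling and RNA quality were not tested, and neither was any other explanation.

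For 15 genes the aPD1 effect differed between B2mKO and WT tumours in edgeR's test of the difference itself (edgeR adjusted p from 0.019 for Lrrtm2 to 0.0448 for Slc4a11; log2 difference ± SE, n = 5 per group). The effect was lower in B2mKO tumours for Cd274 by -2.2 ± 0.4, Gbp4 by -1.7 ± 0.34, Gbp7 by -1.5 ± 0.26, Irgm1 by -1.21 ± 0.23 and Tap2 by -0.75 ± 0.15. It was also lower for Il2rg (-1.74 ± 0.32), the bacterial sensor gene Nod2 (-1.77 ± 0.34), the nucleotide hydrolase gene Samhd1 (-1.33 ± 0.26), Slco3a1 (-2.03 ± 0.4), Heatr9 (-1.92 ± 0.37), Slc4a11 (-1.48 ± 0.31), Lrrtm2 (-1.29 ± 0.21) and Nab1 (-0.57 ± 0.11). For Kcne3 (3.33 ± 0.58) and Rwdd2a (1.57 ± 0.31) it was higher. Nod2, Heatr9, Samhd1, Slco3a1, Rwdd2a and Slc4a11 lie outside the rule for named genes and are given because they complete the 15. Leaving out 1 library changed the count: it was 0 without WT aPD1 replicate 2 or 5 or WT IgG1 replicate 1, and 1, 9 and 154 without WT aPD1 replicates 1, 3 and 4. It was 7, 158 and 2 without WT IgG1 replicates 3, 4 and 5, and 23, 4 and 3 without B2mKO aPD1 replicates 1, 2 and 3. Without B2mKO IgG1 replicates 2, 4 and 5 it was 9, 4 and 9. It was 1 without both WT IgG1 replicate 3 and B2mKO aPD1 replicate 2, and 7 of 100 splits of the libraries gave as many genes, so chance is not excluded.

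Camera with the preset correlation also called 15 lists as differing in the aPD1 effect between B2mKO and WT tumours, given here as the mean log2 difference over a list's genes. The effect was lower for the lists interferon gamma response -1.6, MHC class II -1.24, cytotoxic genes -1.18, granzymes -1.16, checkpoints -1.1, T cells -1.05, regulatory T cells -1.01 and neutrophils -0.66. MHC class I (-0.44), JAK-STAT components (-0.42), type I interferon response (-0.28), mitochondrially encoded genes (-0.46) and ADAM and ADAMTS proteases (-0.19) were lower too, and endothelial (0.47) and proliferation genes (0.16) higher. For these 15, adjusted p = 0.469 to 0.793 with an estimated correlation.

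Between Jak1KO and WT tumours camera called 17 lists. The means were -1.94 for MHC class II, -1.51 for T cells, -1.49 for checkpoints, -1.34 for the interferon gamma response, -1.3 for cytotoxic genes, -1.18 for regulatory T cells, -1.12 for NK cells, -0.92 for neutrophils and -0.81 for granzymes. Macrophages and monocytes (-0.54), MHC class I (-0.44), JAK-STAT components (-0.36), cathepsins (-0.24) and chemokines (-0.18) were lower as well, and skeletal muscle (2.57) and unfolded protein response genes (0.13) higher. The simple epithelial list was at -4.01, a mean that rests in part on fitted values of Krt8 and Krt18, with 2 and 3 counts in the Jak1KO aPD1 group. For these 17, adjusted p = 0.0893 to 0.554 with an estimated correlation.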

How the results depend on the processing

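The tests chosen after seeing the data were the fit without WT IgG1 replicate 3 and B2mKO aPD1 replicate 2, the removal of a trend with transcript length, and the exact permutation of list means. Over all settings, 722 results for named genes gave 17313 values: 16552 kept direction and side of the threshold, 615 lost their call, 122 gained one, 0 reversed a call, and 24 changed sign without a call. The 143 list results gave 2862 values: 2322 kept, 537 lost the call and 3 reversed. With replicate number as a block the gene counts were 564, 0, 0, 12, 0, 3091, 2679, 2993, 3062 and 4302, in the order of the report. The numbers do not pair the libraries: 75 same-number pairs had correlations of -0.59 to 0.46 (mean -0.018), and 5 of 30 libraries correlated best with their own number. Genes with at most 3 counts in a group, such as Hpse2 and Strc, are limited by depth. Unless a reason is given, the cause was not tested.

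Stricter thresholds pass fewer genes by construction. With an absolute log2 fold change of at least 1, WT aPD1 had 373 genes, B2mKO against WT 769 (IgG1) and 943 (aPD1), Jak1KO against WT 784 and 1037, and B2mKO against Jak1KO 1039. With an adjusted p under 0.01 these were 214, 1698 and 1746, 1521 and 1903, and 2807, and the B2mKO difference in aPD1 effect had 0 by edgeR (2550 at an unadjusted p under 0.05).

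For lists, camera with an estimated correlation called 0 in 9 comparisons and 1 in B2mKO against Jak1KO. Exact permutation of list means called 0 for aPD1 in WT, B2mKO and Jak1KO tumours (16, 0 and 0 lists at an unadjusted exact p under 0.05), 0 for B2mKO against WT under IgG1 and 0 under aPD1 (15 and 15), 7 and 11 for Jak1KO against WT (IgG1, aPD1) and 8 for B2mKO against Jak1KO. Over 42 lists, even the smallest exact p, 0.00794, passes only when several lists reach it, and 3, 6 and 3 did for aPD1 in WT tumours and for B2mKO against WT under IgG1 and aPD1, so a count of 0 there says little. Fry called 0 and 0 for aPD1 in B2mKO and Jak1KO tumours, and 3 and 3 for the differences in aPD1 effect in B2mKO and Jak1KO tumours. It called 12 for aPD1 in WT tumours, 13 and 13 for B2mKO against WT, 8 and 18 for Jak1KO against WT and 23 for B2mKO against Jak1KO.

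Without a filter beyond 1 count, 448 genes and 3 proteases passed for WT aPD1 and 6 genes for the B2mKO difference. DESeq2's Wald test gave 17 proteases for WT aPD1, 121 genes and 1 protease for the B2mKO difference and 51 genes for the Jak1KO difference. A fit of only the groups compared gave 55 genes and 1 protease for WT aPD1 and 9 for the B2mKO difference. It gave 1444 and 1780 for B2mKO against WT (IgG1, aPD1), 1641 and 4748 (3221 in the main fit) for Jak1KO against WT and 3364 (4461) for B2mKO against Jak1KO. The main fit pools the groups' unequal spreads, so its 679 for WT aPD1 may be too high.

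Without WT IgG1 replicate 3 and B2mKO aPD1 replicate 2, WT aPD1 had 18 proteases, B2mKO aPD1 4 lists with the proteasome list reversed to -0.055, the B2mKO difference 1 gene, Jak1KO against WT under aPD1 5236 genes and B2mKO against Jak1KO 11 lists. With the length trend removed, WT aPD1 had 18 proteases, B2mKO aPD1 7 lists and the B2mKO difference 23 genes.

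With 1 library left out, WT aPD1 had 230 (without WT aPD1 replicate 2) to 1107 genes (without replicate 4), the B2mKO difference 0 (without WT aPD1 replicate 2) to 158 (without WT IgG1 replicate 4) and the Jak1KO difference 0 to 128 (without WT aPD1 replicate 4). B2mKO aPD1 had 5 (without B2mKO aPD1 replicate 2) to 17 lists, Jak1KO aPD1 6 to 15 (without Jak1KO IgG1 replicate 2) and B2mKO against Jak1KO 12 (without B2mKO aPD1 replicate 2) to 22. The proteasome list in B2mKO aPD1 ranged from -0.05 (reversed, without B2mKO aPD1 replicate 2) to 0.202, and the checkpoint list in Jak1KO aPD1 from -0.457 to -0.022 (without Jak1KO aPD1 replicate 4, where camera's direction reversed). Genotype counts stayed within 1.5 times: 2315 to 3930 and 2418 to 3298 for B2mKO against WT (IgG1, aPD1), 2234 to 3014 and 2417 to 3300 for Jak1KO against WT, and 3729 to 4612 for B2mKO against Jak1KO.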

Other observations

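The tests of reads shared between granzyme copies, of a lower share of tumour cells and of loss of B2m were chosen only after the result was seen. The tests on chromosome windows, shared genes, the genes that rose in WT tumours and other splits were planned beforehand.

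Of 21 JAK-STAT components and receptors, 6 rose with aPD1 in WT tumours (10 adjusted over the list alone; adjusted p = 0.187 with an estimated correlation; exact permutation adjusted p = 0.0742), among them the feedback inhibitor gene Socs1 (0.99 ± 0.19, edgeR adjusted p = 0.00292). The integrin gene Itgax (1.36 ± 0.29) and the itaconate-producing enzyme gene Acod1 (2.08 ± 0.46) rose as well. Of 20 genes of hypoxia and glycolysis, 4 were lower in B2mKO than in WT tumours under IgG1 (7 adjusted over the list alone; adjusted p = 0.727 with an estimated correlation; exact permutation adjusted p = 0.432 for the list mean). All 4 (Ldha, Pgk1, Ndrg1 and Ero1l) missed the threshold without WT IgG1 replicate 3 (edgeR adjusted p = 0.0626, 0.187, 0.105 and 0.0725), and each without at least 1 other library. Under aPD1 5 were lower (6 adjusted over the list alone; adjusted p = 0.916 with an estimated correlation; exact permutation adjusted p = 0.125), with Egln3, a prolyl hydroxylase gene, at -1.16 ± 0.3 (edgeR adjusted p = 0.00558) and Pfkp, of glycolysis, at -0.58 ± 0.15 (edgeR adjusted p = 0.00636). Ero1l and Hk2 missed it without WT aPD1 replicate 1 (0.0604 and 0.099) and without some other libraries. In Jak1KO tumours under IgG1, 4 were lower (4 adjusted over the list alone; adjusted p = 0.919 with an estimated correlation; exact permutation adjusted p = 0.167), with the carbonic anhydrase gene Car9 at -1.78 ± 0.44 (edgeR adjusted p = 0.00459). The other 3, P4ha1, Ndrg1 and Tpi1, missed it without WT IgG1 replicate 3 (0.0764, 0.0663 and 0.127) and without some other libraries.

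Of 25 protease inhibitor genes, 6 were lower in Jak1KO than in WT tumours under aPD1 (6 adjusted over the list alone; adjusted p = 0.569 with an estimated correlation; exact permutation adjusted p = 0.1), with Spint1 at -2.23 ± 0.36 and Timp3 at -1.57 ± 0.32. Further lists were compared between B2mKO and Jak1KO tumours under aPD1. Of 15 unfolded protein response genes, 7 were higher and 1 lower (the same counts adjusted over the list alone; adjusted p = 0.433 with an estimated correlation), such as Pdia4 (0.75 ± 0.08), Xbp1 (0.77 ± 0.11) and Dnajb9 (1.17 ± 0.19). Of 21 JAK-STAT genes, 9 were higher and 1 lower (11 and 1 adjusted over the list alone; adjusted p = 0.398 with an estimated correlation), such as Irf9 (1.94 ± 0.17), Stat2 (1.97 ± 0.19) and Stat3 (0.92 ± 0.14). Of 17 endothelial genes, 7 were higher (9 adjusted over the list alone; adjusted p = 0.539 with an estimated correlation), such as Cldn5 (2.18 ± 0.34) and Pecam1 (0.74 ± 0.18). Of 31 collagen and matrix genes, 16 were higher and 1 lower (the same counts adjusted over the list alone; adjusted p = 0.539 with an estimated correlation), such as Col5a2 (1.59 ± 0.27) and Postn (1.47 ± 0.29). By exact permutation of list means the adjusted p was 0.0417 for the JAK-STAT list, 0.0769 for the unfolded protein response, 0.104 for endothelial and 0.118 for collagen genes.

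Granzyme and NK cell genes were higher in B2mKO than in WT tumours under IgG1. The summed granzyme level differed by 3.64 log2 CPM (9.23 ± 1.16 against 5.58 ± 1.1, SD, n = 5; exact permutation p = 0.00794, adjusted 0.0265). With 6 of 9 genes higher and 0 lower, the sum had to rise, so it cannot weigh reads shared by copies. A lower share of tumour cells would raise other host markers alike. Granzyme and NK genes exceeded the macrophage, neutrophil and dendritic cell lists by 1.76 more in B2mKO tumours (-0.95 ± 0.74 against -2.7 ± 0.43; exact permutation p = 0.00794, adjusted 0.0265). Those lists differed little (0.3, 0.14 and -0.11), while other host lists went both ways without passing by exact permutation of list means. T cell (0.6), regulatory T cell (0.62), B and plasma cell (0.52) and fibroblast genes (0.48) were higher, and mast cell (-0.49) and adipocyte genes (-0.85) lower. The comparison with the myeloid lists was chosen after seeing these data and holds the genes that define the pattern. It therefore cannot decide, and a lower share of tumour cells stays open. The first comparison tried, the NK list minus the macrophage list, had left it undecided (0.96, exact permutation p = 0.0635, adjusted 0.0706). Loss of B2m may contribute, as the granzyme list mean was also higher in B2mKO than in Jak1KO tumours under aPD1 by 2.59 (4.34 ± 1.02 against 1.76 ± 1.26; exact permutation p = 0.0238, adjusted 0.034). Against WT tumours under aPD1 it was higher by 1.29 (3.05 ± 0.42 in WT; exact permutation p = 0.0476, adjusted 0.133 over the lists). These comparisons cannot tell loss of B2m from other differences between the lines, which stay open, untested.

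Chromosome segments with another copy number could give many genotype differences, so the median change was taken in 259 windows of 10 Mb. Of the windows, 6 were shifted by 0.3 or more in B2mKO against WT tumours under IgG1 (at most 4 in 1000 shufflings of the genes) and 9 in Jak1KO against WT (at most 3), such as chromosome 4 from 40 to 50 Mb (93 genes, -0.54) in Jak1KO tumours. Shifted windows held 2.42% (71 of 2928) and 5.34% (136 of 2549) of the called genes that lie in the windows (1.01% and 2.04% of all genes there), which argues against segments shifted by that much as the main cause of these 2 counts. In B2mKO against Jak1KO tumours under aPD1, 26 windows were shifted (at most 5 in the shufflings), with 14.1% of called genes (575 of 4067) and 8.81% of all genes. Effects of the mutations and other differences between the lines were not separated.

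The 579 genes that rose with aPD1 in WT tumours were followed as a set, with an average rise there of 1.17 log2 CPM, which their choice ensures. In B2mKO tumours the difference was 0.1 (exact permutation p = 0.238, and 0.0476 against a rise of 0.3, n = 5 per group), which argues against a rise of 0.3. In Jak1KO tumours it was 0.05 (exact permutation p = 0.841, and 0.286 against 0.3), which leaves a rise open. Against WT, the knockouts shared 234 higher and 413 lower genes under IgG1 (105 and 200 for independent lists) and 327 and 660 under aPD1 (128 and 202). Pairs of comparisons with no library in common shared 193 and 291 (122 and 224 for independent lists) and 182 and 347 (111 and 180). The lowest of these ratios was 1.3. With the WT IgG1 libraries split so that the comparisons shared none, 3 splits still gave 252 to 303 shared genes against 126 to 209. How far shared WT libraries account for the rest was not separated from effects common to the knockouts.

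Other splits of the same libraries into groups of the same sizes, 100 per comparison, were analysed in the same way, counting those with a result at least as large, the real one included. For aPD1 in WT tumours 3 splits had as many as 679 genes (highest other 1048). The real gene count was the highest of the 100 splits (1 split) for B2mKO against WT under IgG1 (3270, highest other 2215) and aPD1 (3158, 2564). It also was for Jak1KO against WT (2833, 399, and 3221, 1226) and B2mKO against Jak1KO (4461, 1644). These shares are under 0.05 but not adjusted over the comparisons, so chance is unlikely and not excluded. It stays open for the B2mKO difference in aPD1 effect, where 7 splits had 15 or more (highest other 909). For counts of 0 by edgeR, as in aPD1 in B2mKO tumours (highest other 693; 511 genes at an unadjusted p under 0.05), aPD1 in Jak1KO tumours (11; 172 genes) and the Jak1KO difference (40; 1279 genes), all 100 splits are as large. Splits with 693, 909 and 1048 genes, up to many times the real count, point to a structure of the samples that the groups do not describe.

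For proteases the real count was the highest of the 100 splits for B2mKO against WT under aPD1 (38 genes, 1 split, highest other 35). The same holds for Jak1KO against WT (34, 1 split, 10, and 48, 1 split, 27) and B2mKO against Jak1KO (59, 1 split, 31). Other splits reached the real count for aPD1 in WT tumours (10, 3 splits, 27) and B2mKO against WT under IgG1 (30, 2 splits, 32). In all of these chance is unlikely, without adjustment over the comparisons, and not excluded. A protease count rises with the count over all genes, so these splits are no separate test of proteases. With a real count of 0 by edgeR, all 100 splits were as large for aPD1 in B2mKO (highest other 9) and Jak1KO tumours (0) and for the B2mKO (13) and Jak1KO differences (0). For camera's list counts chance stays open in every comparison. For aPD1, 28 splits had 16 or more lists in WT tumours (highest other 24), 34 had 13 or more in B2mKO (21) and 78 had 9 or more in Jak1KO tumours (27). For the differences in aPD1 effect, 41 had 15 or more (22) in B2mKO and 28 had 17 or more (29) in Jak1KO tumours. Under IgG1, 16 had 15 or more (20) for B2mKO against WT and 64 had 10 or more (25) for Jak1KO against WT. Under aPD1 these were 61 with 11 or more (24) and 48 with 16 or more (27), and 19 had 21 or more (29) for B2mKO against Jak1KO.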
